A study of Mus musculus with 5 samples.

How the data were processed

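Spermatocytes and spermatids were collected from male C57Bl/6 mice by sedimentation at unit gravity, and stranded libraries of polyadenylated RNA were made from total RNA, per the labels' protocols. The deposited table holds a normalized signal per gene and sample, gene counts that the authors divided by a size factor for each library with DESeq, per the file headers and the submitters' processing notes. These notes also name FastQC, Picard, SAMtools, STAR 2.4.0 and the mouse build mm10, with no role or order. The file header names GenoSplice gene identifiers and mm10 coordinates. The program that counted reads, its strand setting and its treatment of reads that match several genes are not given in the sources used here. Without the strand setting, reads of overlapping genes cannot be told apart, and 25 of the 68 named genes overlap another row of the table.

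The table has 56324 rows, of which 32111 carry no gene symbol and 234 carry several. Every value was a whole multiple of the smallest value of its column, within 0.001, for 100% of the values, so whole reads were recovered by dividing by it. The totals were 52784231 to 84361908 reads per library. In each library more genes had 2 reads than 1, for example 3423 against 1895 in spermatocyte replicate 1, and the reason was not tested. If fragments were counted by their ends, reads are not independent molecules and counting intervals are too narrow; intervals and floors cover counting error only. The totals of the normalized values were 56855924 and 53899393 in spermatocytes and 96511989, 83611275 and 80600836 in spermatids, so the authors' size factors and equal library totals give different zero points.

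Groups were taken from the cell type labels, and replicates were numbered in accession order, which pairs no samples. The design, the 22 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. Genes with a mean value of at least 10 over the 5 samples were tested with limma 3.58.1 in R 4.3.3 on log2(value + 1), with eBayes and a mean-variance trend, and Benjamini-Hochberg adjustment at 0.05. Fold changes are on this log2(value + 1) scale, which understates the change of low genes. Where a group had no read, the fold is given as a bound against 3 reads in each of its libraries, and with 1 to 3 reads as a ratio with an exact 95% Poisson interval. Lists and X-linked genes were compared with all other tested genes by camera with a preset correlation of 0.01, adjusted over the 22 sets tested, and again with a correlation estimated from 3 residual degrees of freedom. No set passed with the estimated correlation. This setting was not tried in the simulations, so how often it would call a changed set is not known. List members were matched by the symbols in the table, and rows with several symbols were left out unless all belonged to the list. The mitochondrial list matched 0 of 13 members and the Y-linked list 9 of 16.

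The named genes were the 10 with the largest log2 fold change in each direction among those past the threshold, with a mean of at least 100 in the higher group, no overlap between the groups and a symbol that is not a Gm number, Rik clone, LOC, ENSMUSG or pseudogene name; the 2 members of each list with the highest mean over the 5 samples; and every tested transition protein and protamine gene. Rows with no symbol or with several were also passed over in the first part. A gene that the rule selects is not reported here. Transcript lengths came from GENCODE vM21 by symbol.

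Recovered reads were tested with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0, both with the authors' size factors. They called 21931 and 21784 genes, against 21871 with limma, of which 21749 and 21576 were also limma calls in the same direction. The other alternatives were other pseudocounts, filters, scalings and eBayes settings, and leaving out each replicate. Summaries were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots with matplotlib 3.10.9.

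The limma and camera steps were tested on simulated counts for spermatids against spermatocytes, drawn from the real means, library sizes and dispersions with 200 genes changed. Of 27889 genes tested, 21% of 100 genes changed by 2-fold and 73.7% of 99 changed by 4-fold were called in the right direction. A target of 80% recovery at 4-fold, set when the test was written, was missed and was then replaced by criteria on the size of the folds, the p-values and false calls. The estimated sizes were unbiased (median absolute log2 fold change 1.00 and 1.98), and 4.51% of unchanged genes had an unadjusted p under 0.05. The genes missed were mainly low: at means over 1000, 19 of 32 genes changed by 2-fold and 24 of 24 changed by 4-fold were called, against 0 of 23 and 1 of 20 at means of 10 to 30. Of the 106 calls 12 were false, 11.3%, above the nominal 5%. Camera with the preset correlation gave p = 5.5e-144 for a set of genes raised 4-fold and camera p = 0.63 for an unchanged set. Genes were simulated independently of each other. The simulation therefore cannot show whether camera p-values hold for lists whose genes move together. A second simulation, added after the first and with 75% of genes changed, recovered 76.7% at 2-fold and 97.7% at 4-fold over 28043 genes, with 1.13% of calls false.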

Results

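Messenger RNA was sequenced from purified male germ cells of C57Bl/6 mice aged 12 weeks. There were 2 samples of spermatocytes, the cells that carry out meiosis, and 3 samples of spermatids, the haploid cells that form after it and shape themselves into sperm. Both fractions were obtained by sedimentation at unit gravity, which separates cells mainly by size. The reads recovered from the deposited values came to 52784231 and 80384019 for spermatocyte replicates 1 and 2, and to 62249782, 84361908 and 76907629 for spermatid replicates 1, 2 and 3. The series title concerns the retention of introns in transcripts during meiosis. Introns were not analysed here, because the table gives 1 value per gene. The comparison is therefore of gene levels, spermatids against spermatocytes. The labels do not say whether the samples came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

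Most of the measured transcriptome differed between the cell types. Of 28370 genes tested, 11512 were higher in spermatids and 10359 were higher in spermatocytes (limma, Benjamini-Hochberg adjusted p under 0.05). Differences of at least 2-fold were found for 9421 genes in the direction of spermatids and for 8147 in the direction of spermatocytes. Very large differences were mostly in 1 direction: 2717 genes were at least 32-fold higher in spermatids and 430 at least 32-fold higher in spermatocytes. The values of the groups did not overlap for 24346 of the 28370 genes tested, 85.8%, where chance alone gives such a separation for 20% of genes. The split of calls depended on the scaling and on the filter for low values. With the deposited values 52.6% of the calls were higher in spermatids, against 38.1% when each library was rescaled to the same total and 41.3% after quantile normalization. With TMM factors this share was 50.4%, near that of the deposited values. With no filter on low values, 12999 genes were higher in spermatids and 17263 in spermatocytes, so the balance turned. With a mean of at least 100 the counts were 7957 and 6029. The median log2 fold change over all genes was 0.07 as deposited, -0.02 with TMM factors, -0.57 with equal totals and -0.42 after quantile normalization. Directions below are therefore relative to the deposited scaling, and small changes that turn with it are named.

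The genes with the largest differences toward spermatids included several with no read in either spermatocyte library. Slx, an X-linked gene present in many copies and expressed after meiosis, had a normalized count of 2318 ± 221.9 (SD, n = 3) in spermatids and 0 in both spermatocyte samples, which makes it at least 884-fold higher against a floor of 3 reads per library. On the same floor the homeobox gene Rhox3c was at least 132-fold higher, the transcription factor gene Foxp2 at least 114-fold, Apol10a at least 81.3-fold and Pcsk1, a prohormone convertase gene, at least 77.7-fold. Hsd3b4 and Calml3, a calmodulin-like gene, each had 1 read in spermatocytes and were 713-fold (95% counting interval 128.0 to 28169) and 721-fold (129.4 to 28483) higher in spermatids. These intervals cover counting error only. Calml3 was at 547 in spermatid replicate 1 and at 149 and 198 in replicates 2 and 3, so its fold rests in part on replicate 1. Hrh2, the gene of a histamine receptor, had 2 reads in spermatocytes and was 334-fold higher (92.3 to 2755). Sirpb1c changed from 3.16 ± 1.62 (SD, n = 2) to 1011 ± 93.2 (SD, n = 3), and the olfactory receptor gene Olfr127 from 2.15 ± 3.05 to 453 ± 73.6. Slx, Rhox3c, Sirpb1c, Apol10a, Hsd3b4 and Olfr127 belong to families of similar genes whose reads the counting could have shared out, so their levels are uncertain. The row of Foxp2 overlaps 9 other rows of the table and that of Slx overlaps 1. Without the strand setting, reads of these rows cannot be told apart, so the level of Foxp2 is also uncertain.

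Among the genes with the largest differences toward spermatocytes, Helt, a gene of a transcriptional repressor, had a normalized count of 158 ± 36.7 (SD, n = 2) and no read in any spermatid library, at least 44.1-fold higher in spermatocytes. Slc13a2 had 3 reads in the spermatid libraries and was 152-fold higher in spermatocytes (95% counting interval 52.0 to 736). Dmrta1 was at 1091 ± 236 in spermatocytes and 13.04 ± 5.31 in spermatids, and Islr2 at 1022 ± 384 and 11.8 ± 9.06. The X-linked Mageb16, a melanoma antigen family gene, was at 947 ± 134 and 11.3 ± 9.79, and its log2 fold change of -7.10 had a standard error of 1.24. Gpr37, Edn1, the gene of endothelin, Sox8 and D3Bwg0562e fell from means of 504, 292, 188 and 382 to means of 5.70, 3.75, 1.98 and 3.05. The row that carries the symbol Mir34a spans chromosome 4 from 150068454 to 150070999 (mm10), far more than a microRNA hairpin, and fell from 575 ± 43.5 to 6.73 ± 4.92. It therefore measures the longer transcript and not the mature microRNA. Passing the limma test was a condition for choosing these 10 genes, and their limma adjusted p ran from 7.1e-06 (Helt) to 0.0016 (Mageb16). Each of the 10 was higher in spermatocyte replicate 2 than in replicate 1, for example Sox8 at 242 and 134. The median log2 ratio of replicate 1 to 2 was 0.03 over all tested genes. Sertoli cell markers were also higher in replicate 2, for 25 of 26 members. Whether the 10 transcripts came from spermatocytes or from Sertoli cells was not tested.

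Transition proteins and protamines, which replace histones as the spermatid nucleus condenses, were higher in spermatids for 8 of 8 genes, over all genes tested and adjusted over the list alone. Prm2 rose from 5240 ± 1329 (SD, n = 2) to 288073 ± 255606 (SD, n = 3), Prm1 from 1767 ± 110 to 124351 ± 101709, Tnp2 from 3464 ± 338 to 220205 ± 141626 and Tnp1 from 1834 ± 478 to 126584 ± 84559. The log2 fold changes ran from 5.45 ± 0.61 (SE) for Prm2 to 6.24 ± 0.30 for H1fnt, a linker histone gene of spermatids. Hils1, another linker histone gene, reached 58854 ± 6502, Prm3 12700 ± 4589 and 1700024P04Rik, a histone variant gene, 11041 ± 5833. Spermatocyte levels of all 8 genes were within the small share of the spermatid level that abundant spermatid genes have in common, given under other observations. If spermatid RNA or reads entered the spermatocyte libraries, which stays open, these folds are too small. The list median was 5.98 (camera adjusted p = 0.0012). With an estimated correlation the list was not past the threshold, adjusted p = 0.58. Spermatid replicate 1 held more of these transcripts than the other spermatid samples: Prm2 was 583221 there against 140587 and 140411, and the list's median log2 ratio of replicate 1 to the mean of replicates 2 and 3 was 1.34, against 0.01 for all tested genes. The same median ratio was -0.72 for Leydig cell markers and -0.53 for myoid, endothelial, macrophage and blood markers. Prm1, Prm2, Prm3 and Tnp2 lie together on chromosome 16 between 10787936 and 10796827 (mm10).

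**Figure D1:**
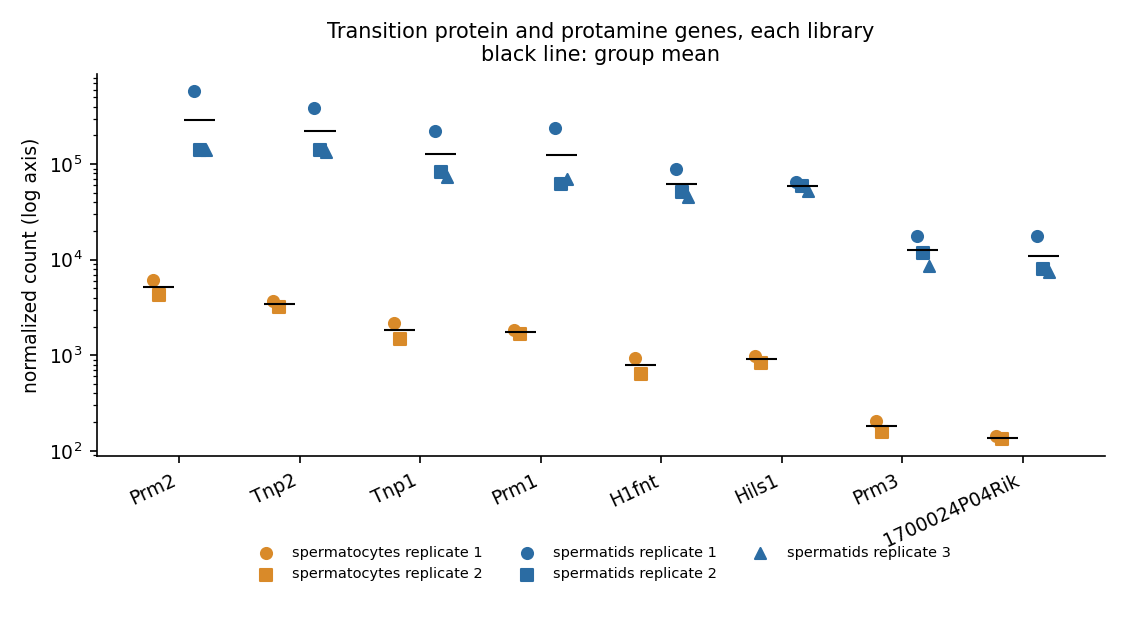
Normalized counts on a log axis of the 8 transition protein and protamine genes in each of the 5 libraries, with marks for replicates and black lines for group means. All 3 spermatid samples lie above both spermatocyte samples for each gene, and spermatid replicate 1 is the highest spermatid sample for each gene.

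Genes of the acrosome, the vesicle at the head of the sperm that opens at fertilization, were higher in spermatids for 32 of 37 tested members and lower for 1, and 20 of the 37 were at least 32-fold higher. Adjusted over the list alone the counts were also 32 and 1, with equal totals 25 and 7, and after quantile normalization 26 and 7. The list median was 5.32 (camera adjusted p = 3.3e-07), and it was not past the threshold with an estimated correlation, adjusted p = 0.58. The 2 most abundant members had changes far below the list median: Atp8b3, the gene of a lipid flippase, went from 138273 ± 8851 to 281457 ± 18959, a log2 fold change of 1.02 ± 0.10 (SE), and Adam5 from 107094 ± 5434 to 161032 ± 24652, a log2 fold change of 0.58 ± 0.14. Adam5 turned to -0.07 with libraries rescaled to the same total, and its call ended after quantile normalization (limma adjusted p = 0.54) and without spermatocyte replicate 2 (0.071).

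Of 37 sperm tail genes, 29 were higher in spermatids and 5 lower, in both adjustments (list median 1.51, camera adjusted p = 8.0e-05, adjusted p = 0.58 with an estimated correlation). Both with equal totals and after quantile normalization 23 were higher and 9 lower. Odf2, which encodes a protein of the outer dense fibres, rose from 148191 ± 18395 to 468250 ± 138260, and Tcp11 from 75728 ± 4498 to 202781 ± 37428. Of 26 genes of sperm ion channels and motility signalling, 16 were higher in spermatids and 5 lower, or 17 and 5 adjusted over the list alone (median 0.59, camera adjusted p = 0.0077, adjusted p = 0.58 with an estimated correlation). Atp1a4, the sperm form of the sodium pump, rose from 1356 ± 341 to 108924 ± 33882, whereas Ppp3r2, a calcineurin subunit gene, was at 67506 ± 2306 and 63424 ± 791 (limma adjusted p = 0.34). Ppp3r2 was called lower in spermatids with equal library totals (log2 fold change -0.74, limma adjusted p = 0.00026) and after quantile normalization (-0.69, limma adjusted p = 0.0012). With equal totals the channel list had 12 members higher and 11 lower, and with quantile normalization 11 and 13, and its call ended under both (camera adjusted p = 0.075 and 0.22).

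Germ cell glycolysis and energy metabolism had 18 of 27 members higher in spermatids and 6 lower, in both adjustments (median 1.48, camera adjusted p = 0.033, adjusted p = 0.67 with an estimated correlation), against 14 and 9 with equal totals and 15 and 10 after quantile normalization. Hk1, the gene of a hexokinase, rose from 25881 ± 2898 to 264364 ± 73038. Ldhc, the lactate dehydrogenase of germ cells, had high values in both groups, 303628 ± 31109 and 348695 ± 15814 (limma adjusted p = 0.12), and was lower in spermatids with equal totals (log2 fold change -0.45) and after quantile normalization (-0.53). The call on this list ended without spermatocyte replicate 2 (camera adjusted p = 0.081), after quantile normalization (0.088) and with a mean of at least 100 (0.11).

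Transcription regulators of the germ line were higher in spermatids for 26 of 34 members and lower for 4, or 27 and 4 adjusted over the list alone (median 1.69, camera adjusted p = 0.00048, adjusted p = 0.58 with an estimated correlation). With equal totals 19 were higher and 10 lower, and after quantile normalization 19 and 11. Spz1, a zipper-domain factor gene of the testis, rose from 2602 ± 516 to 158403 ± 75556, with 245447 in spermatid replicate 1 against 120004 and 109759. Kctd19, which is needed for meiosis, was at 69386 ± 2731 and 69464 ± 719 (limma adjusted p = 0.98), and was called lower in spermatids with equal totals and after quantile normalization.

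**Figure D2:**
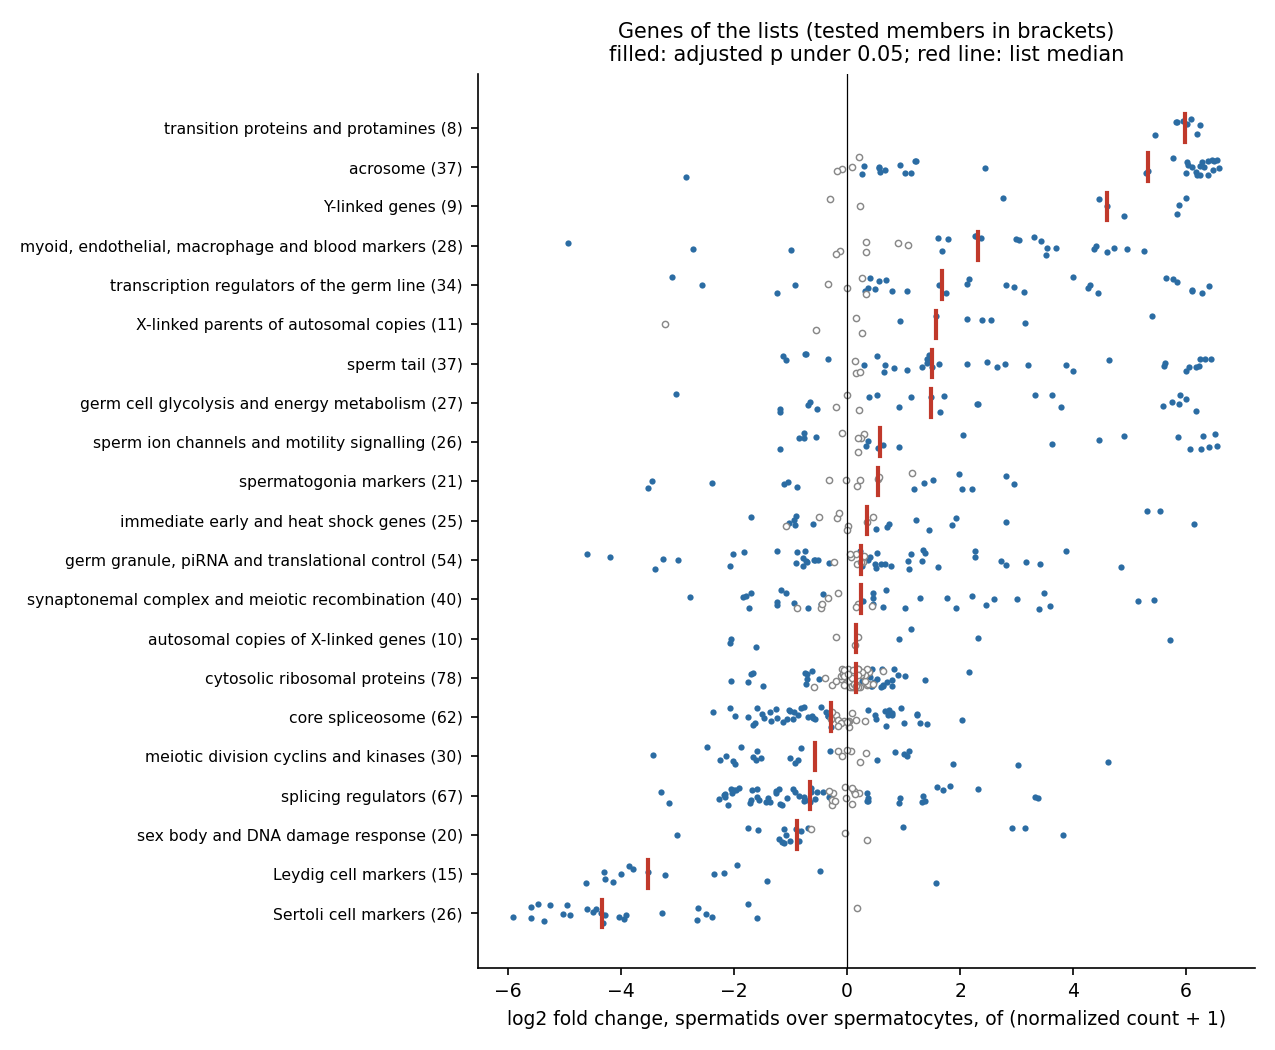
The log2 fold change of each tested member of the gene lists, spermatids over spermatocytes, with filled points for genes past the threshold and a red line at each list's median. The medians run from -4.34 for Sertoli cell markers to 5.98 for transition proteins and protamines.

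More splicing genes were lower than higher in spermatids. Of 62 core spliceosome genes, 32 were lower and 16 higher in both adjustments (median -0.29, camera adjusted p = 0.033, adjusted p = 0.67 with an estimated correlation), and of 67 splicing regulators 40 were lower and 15 higher in both adjustments (median -0.65, camera adjusted p = 0.00081, adjusted p = 0.58 with an estimated correlation). With equal totals 47 core genes were lower and 7 higher, and 55 regulators lower and 9 higher. After quantile normalization these counts were 45 and 7, and 55 and 10. The most abundant members did not follow their lists. Sf1, whose protein binds the intron branch point, rose from 14389 ± 1128 to 35146 ± 1774, and Son from 42957 ± 1288 to 55160 ± 5599, while Dhx16 (14194 ± 457 and 14491 ± 1140, limma adjusted p = 0.81) and Hnrnpf (42041 ± 2046 and 44730 ± 3538, limma adjusted p = 0.44) were not past the threshold. Son, Dhx16 and Hnrnpf were called lower in spermatids with equal totals and after quantile normalization. The rise of Son was also lost with TMM factors (limma adjusted p = 0.059), without an eBayes trend (0.088), and without spermatocyte replicate 1 (0.084), spermatocyte replicate 2 (0.14) or spermatid replicate 3 (0.070). The core spliceosome call ended with no filter on low values (camera adjusted p = 0.14), without an eBayes trend (0.059), without spermatid replicate 2 (camera adjusted p = 0.058) and without spermatid replicate 3 (camera adjusted p = 0.072).

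Genes of meiosis went both ways. Of 40 genes of the synaptonemal complex and recombination, 19 were higher in spermatids and 13 lower, or 19 and 15 adjusted over the list alone (median 0.24, camera adjusted p = 0.90, adjusted p = 0.95 with an estimated correlation). These counts turned to 11 higher and 20 lower with equal totals and to 12 and 19 after quantile normalization. The cohesin genes Stag3 and Smc1b were its most abundant members. Smc1b rose from 12157 ± 403 to 41516 ± 5163, and Stag3 went from 50529 ± 1591 to 69106 ± 540, a log2 fold change of 0.45 ± 0.08 that turned to -0.20 with equal totals and to -0.16 after quantile normalization. The following members were chosen after their values were seen: Sycp3 (-1.70), Hormad1 (-1.80) and Spo11 (-1.24) were lower in spermatids, whereas Dmc1 (2.21), Prdm9 (2.47), Rec8 (5.15) and Tex15 (5.43) were higher. Of 30 cyclins and kinases of the meiotic divisions, 16 were lower and 8 higher in both adjustments (median -0.56, camera adjusted p = 0.065, adjusted p = 0.67 with an estimated correlation), against 21 and 4 with equal totals and 20 and 6 after quantile normalization. Espl1, the gene of separase, fell from 26430 ± 499 to 14996 ± 1602, and the chaperone gene Hspa2 was at 171715 ± 11439 and 180033 ± 9073 (limma adjusted p = 0.53), and was called lower in spermatids with equal totals (log2 fold change -0.58).

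Of 20 genes of the sex body and the DNA damage response, 13 were lower in spermatids and 4 higher in both adjustments (median -0.88, camera adjusted p = 0.053, adjusted p = 0.58 with an estimated correlation), against 16 and 3 with equal totals and 16 and 4 after quantile normalization. Mdc1, which spreads the damage signal over the sex chromosomes, fell from 27731 ± 1205 to 9253 ± 142. Of 54 genes of germ granules, piRNA and translational control, 26 were higher and 20 lower in both adjustments (median 0.25, camera adjusted p = 0.90, adjusted p = 0.95 with an estimated correlation), counts that became 12 and 30 with equal totals and 13 and 30 after quantile normalization. Pabpc1 rose from 166502 ± 16120 to 219524 ± 9127 as deposited and was called lower with equal totals (log2 fold change -0.25). Its call ended without spermatocyte replicate 2 (limma adjusted p = 0.12), and after quantile normalization its log2 fold change was -0.049 (limma adjusted p = 0.71). Tdrd6 was at 161449 ± 5304 and 168337 ± 7262 (limma adjusted p = 0.56), and was called lower with equal totals and after quantile normalization.

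Both sex chromosomes, which are silenced in the pachytene stage of meiosis, had higher levels in spermatids. Of 828 X-linked genes, 522 were higher and 174 lower, 63.0% against 39.9% of autosomal genes in the direction of spermatids. Adjusted over the X alone the counts were 526 and 177, with equal totals 464 and 227, and after quantile normalization 487 and 202. The X median was 2.32, or 2.37 with the 52 genes that had no read in a group set at their floor, while the medians of single autosomes ran from -0.24 to 0.44. None of 1000 random autosomal lists matched on mean level reached the X median, and 95% of them lay between -0.22 and 0.10. Such lists treat genes as independent, while the estimated correlation among X-linked genes was 0.115, so this range may be too narrow. The X median minus that of other genes was 2.29, against 1.40 with no filter on low values and 3.22 with a mean of at least 100. The camera adjusted p was 2.9e-05, and with an estimated correlation the adjusted p = 0.58. The median X-linked gene had a normalized count of 46.6 in spermatocytes and 142 in spermatids, against 138 and 179 for autosomal genes. Of 9 Y-linked genes, 7 were higher in both adjustments and 2 were not past the threshold (median 4.61, camera adjusted p = 0.0076, adjusted p = 0.58 with an estimated correlation), and 7 were higher and 1 lower both with equal totals and after quantile normalization. Eif2s3y rose from 313 ± 33.1 to 6867 ± 573 and Uba1y from 226 ± 50.6 to 5485 ± 312.

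**Figure D3:**
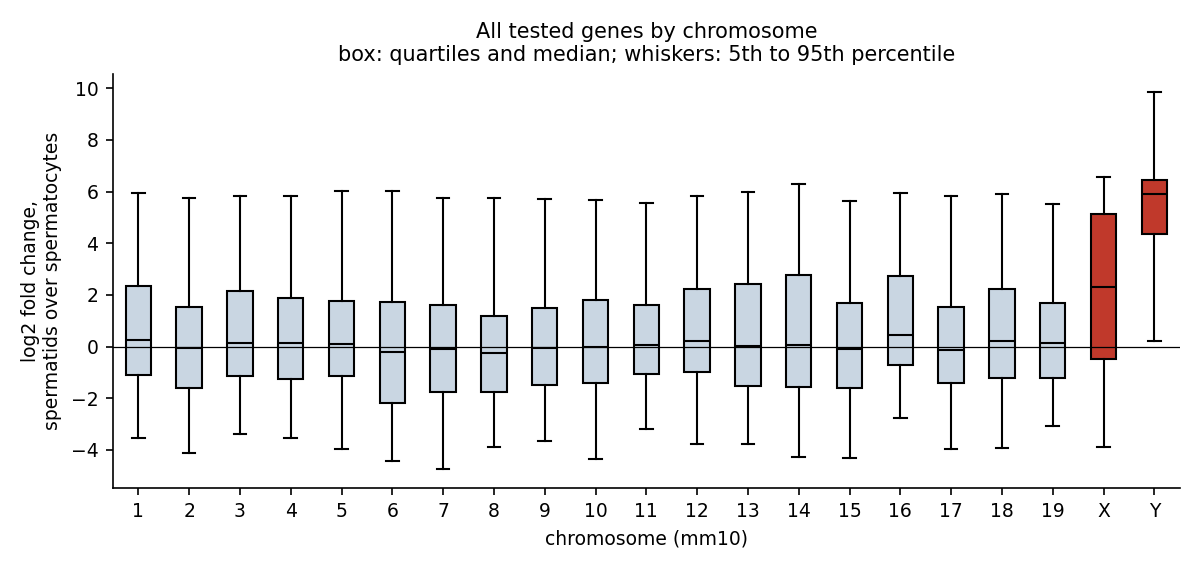
The log2 fold change, spermatids over spermatocytes, of all tested genes by chromosome, with boxes for quartiles and whiskers from the 5th to the 95th percentile. The X and Y medians, 2.32 and 5.90, stand above the autosomal medians of -0.24 to 0.44.

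Autosomal copies of X-linked genes, several of which arose by retroposition, had 4 of 10 members higher in spermatids and 3 lower in both adjustments (median 0.17, camera adjusted p = 0.92, adjusted p = 0.95 with an estimated correlation), and 3 higher and 6 lower both with equal totals and after quantile normalization. Pgk2 rose from 21680 ± 1602 to 110014 ± 30537 and Gk2 from 50690 ± 1430 to 111021 ± 3137. Their X-linked parents had 7 of 11 members higher and none of the 11 lower in both adjustments (median 1.57, camera adjusted p = 0.065, adjusted p = 0.58 with an estimated correlation), and 6 higher and 2 lower with equal totals. Cstf2, of the cleavage stimulation factor, rose from 251 ± 11.4 to 10659 ± 913, and Prps1 from 91.1 ± 11.5 to 546 ± 115. If spermatid RNA or reads entered the spermatocyte libraries, which stays open, the fold of Cstf2 is too small.

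Of 78 cytosolic ribosomal protein genes, 44 were not past the threshold, 23 were higher in spermatids and 11 lower, or 15 higher and 10 lower adjusted over the list alone (median 0.16, camera adjusted p = 0.79, adjusted p = 0.95 with an estimated correlation). With equal totals 2 were higher and 41 lower, and after quantile normalization 4 and 35. Rpl41 was at 19615 ± 684 and 25423 ± 3968 (limma adjusted p = 0.042) and Rplp0 at 21622 ± 2112 and 23304 ± 3282 (limma adjusted p = 0.51). Both were called lower in spermatids with equal totals and after quantile normalization. The call on Rpl41 ended under 7 other alternatives, among them TMM factors (limma adjusted p = 0.084) and leaving out either spermatocyte sample (0.12 and 0.20). Of 25 immediate early and heat shock genes, 11 were higher and 6 lower in both adjustments (median 0.34, camera adjusted p = 0.42, adjusted p = 0.60 with an estimated correlation), and 8 were higher and 10 lower both with equal totals and after quantile normalization. As deposited, Dnajb1 rose from 14667 ± 729 to 24365 ± 477 and Hspa5 was at 31634 ± 367 and 32028 ± 2930 (limma adjusted p = 0.91). Dnajb1 was not past the threshold with equal totals (log2 fold change 0.085, limma adjusted p = 0.49) or after quantile normalization (-0.027, limma adjusted p = 0.82), and Hspa5 was called lower in spermatids under both. The mitochondrial mRNA list could not be tested as planned, since none of its 13 symbols is used in the table. Of 13 rows without these symbols that were tested on the mitochondrial chromosome, 11 were lower in spermatids and 0 higher (median -1.78). All rows placed on the mitochondrial chromosome together held 1.93% and 2.16% of the reads in spermatocytes and 0.48%, 0.41% and 0.36% in spermatids.

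Markers of other testis cells also moved with the groups. Sertoli cell markers, from the somatic cells that enclose germ cells, were higher in spermatocyte samples for 25 of 26 genes in both adjustments (median -4.34, camera adjusted p = 1.4e-08, adjusted p = 0.58 with an estimated correlation). Clu was at 47612 ± 8676 in spermatocytes and 992 ± 247 in spermatids, and Ctsl at 11481 ± 1447 and 789 ± 307. Leydig cell markers, from the steroid-producing cells between the tubules, were higher in spermatocytes for 14 of 15 genes and lower for 1 in both adjustments (median -3.52, camera adjusted p = 0.00081, adjusted p = 0.58 with an estimated correlation). Scarb1, the most abundant, was the exception, at 2106 ± 115 and 6274 ± 582, and Fdx1 was at 2843 ± 127 and 2046 ± 272, a call that ended without an eBayes trend (limma adjusted p = 0.0502) and without spermatocyte replicate 1 (0.091) or 2 (0.056). Myoid, endothelial, macrophage and blood markers went the other way, with 19 of 28 higher in spermatids and 3 lower in both adjustments (median 2.32, camera adjusted p = 0.0090, adjusted p = 0.58 with an estimated correlation), against 17 and 4 with equal totals and 18 and 4 after quantile normalization. Dcn rose from 128 ± 11.7 to 1388 ± 34.3, whereas Myl9 fell from 1301 ± 293 to 200.4 ± 64.1. Of 21 spermatogonia markers, 8 were higher in spermatids and 6 lower in both adjustments (median 0.54, camera adjusted p = 0.90, adjusted p = 0.95 with an estimated correlation), against 7 and 7 with equal totals and 8 and 7 after quantile normalization. Id4 fell from 3700 ± 71.4 to 337 ± 15.6 and Uchl1 from 825 ± 7.36 to 448 ± 55.2.

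Replicates were closer to each other than to the other group. Across genes, Pearson's r of the log2 values was 0.985 between the spermatocyte samples and from 0.977 to 0.987 among the spermatid samples, and from 0.654 to 0.679 between groups. These are correlations across genes, which are not independent replicates. No pair of samples looked like the same library deposited again. The chi-square per degree of freedom, which takes reads as independent and is too large if they are not, was 14.6 for the spermatocytes and 19.7 for spermatid replicates 2 and 3, but 129 and 132 for spermatid replicate 1 against replicates 2 and 3.

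**Figure D4:**
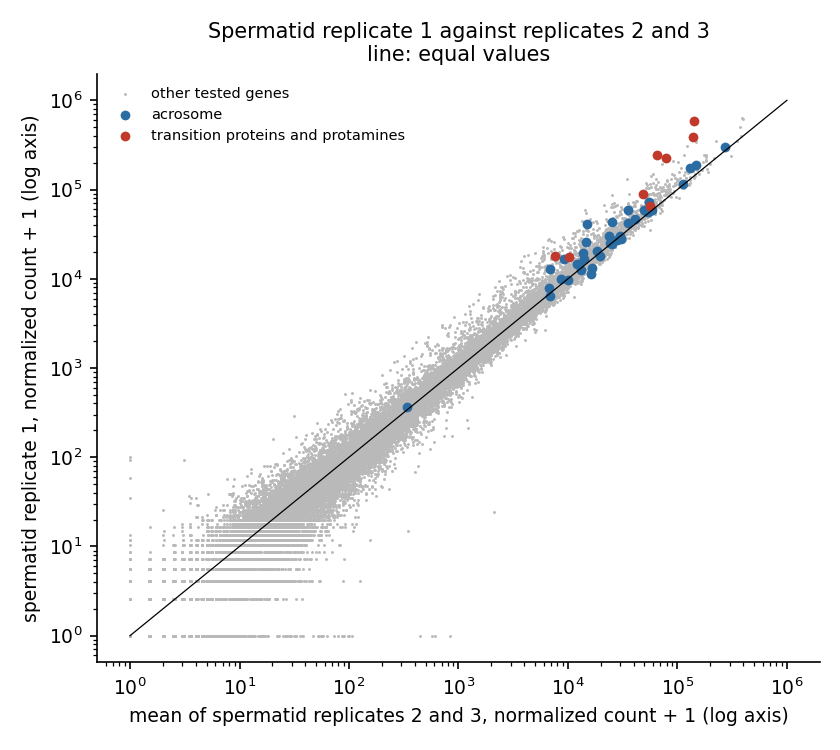
Normalized count plus 1 of each tested gene in spermatid replicate 1 against the mean of replicates 2 and 3, both on log axes, with acrosome genes in blue and transition protein and protamine genes in red. The median log2 ratio is 1.34 for the red genes, 0.22 for the blue genes and 0.01 for all tested genes.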

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

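All alternatives here were planned, and values for lists are the list median minus the median of the other genes in log2. Camera compares gene statistics and not medians, so its direction can differ from the sign of these values, as for ribosomal proteins below. Of 438 alternative values for counts, the X and lists, 366 kept their direction and their side of the threshold, or stayed within 1.5 times for counts. The cause was not tested except where fewer genes were tested. With an estimated correlation 13 sets lost their call, at unchanged values: X-linked genes 2.29, acrosome 5.26, transition proteins and protamines 5.91, sperm tail 1.44, ion channels 0.52, glycolysis 1.41, core spliceosome -0.36, splicing regulators -0.72, transcription regulators 1.62, Y-linked genes 4.54, Sertoli -4.41, Leydig -3.59 and myoid, endothelial, macrophage and blood 2.26. The lowest adjusted p over the sets was then 0.58. With no filter on low values, 17263 genes were higher in spermatocytes, 14847 of them at least 2-fold, against 12999 higher in spermatids. The core spliceosome then lost its call (-0.021) and X-linked parents gained one (1.84). With a mean of at least 100, which tests fewer genes, 6029 were higher in spermatocytes, 3958 at least 2-fold, and 5968 at least 2-fold higher in spermatids; division cyclins (-1.04), sex body (-1.12) and X-linked parents (2.04) gained a call, glycolysis (1.18) lost one, and the synaptonemal complex (-0.035), germ granule (0.023), autosomal copies (-0.050), ribosomal proteins (-0.10) and spermatogonia (-0.24) changed test direction without a call. The sex body list gained a call with pseudocount 0.1 (-0.95), and the core spliceosome lost its call without an eBayes trend (-0.36).

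With each library rescaled to the same total, ribosomal proteins were called lower in spermatids (0.10, test direction reversed), division cyclins gained a call (-0.64), ion channels lost one (0.52), and the synaptonemal complex (0.16), germ granule (0.17) and autosomal copies (0.090) turned without a call. With quantile normalization ribosomal proteins were again called lower (0.024), division cyclins (-0.81), sex body (-0.98) and X-linked parents (1.56) gained a call, ion channels (0.25) and glycolysis (1.32) lost one, and the synaptonemal complex (0.042), germ granule (0.0044) and autosomal copies (-0.15) turned without a call. With TMM factors only ribosomal proteins (0.10) turned, without a call. With edgeR and DESeq2 division cyclins gained a call (-0.64 in both), and germ granule (0.17 in both), autosomal copies (0.078 and 0.080), ribosomal proteins (0.069 and 0.073) and spermatogonia (0.45 and 0.46) turned without a call.

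Of 1085 alternative values for the 68 named genes, 1024 kept direction and side. Direction turned for 25 with a call before or after, all under equal totals or quantile normalization, and for 15 with no call on either side. The log2 fold changes under these scalings, in that order, were -0.20 and -0.16 for Stag3, -0.45 and -0.53 for Ldhc, -0.62 and -0.72 for Dhx16, -0.29 and -0.35 for Son, -0.56 and -0.63 for Hnrnpf, -0.25 and -0.049 for Pabpc1, -0.59 and -0.43 for Tdrd6, -0.65 and -0.57 for Kctd19, -0.28 and -0.39 for Rpl41, -0.55 and -0.63 for Rplp0, and -0.63 and -0.72 for Hspa5. Hspa2 turned under both (-0.58, and -0.45 with no call), Adam5 (-0.069) with equal totals and Dnajb1 (-0.027) with quantile normalization. With no call on either side, TMM factors turned Hspa2 (-0.024), Dhx16 (-0.066), Hnrnpf (-0.0056), Tdrd6 (-0.033), Kctd19 (-0.091) and Hspa5 (-0.079), and leaving out 1 replicate turned Rplp0, Dhx16, Kctd19 and Hspa5. Both scalings lower the median log2 fold change over all genes, from 0.07 to -0.57 and -0.42.

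Leaving out 1 replicate at a time gave ranges of 0.074 to 0.31 for the synaptonemal complex, -0.77 to -0.52 for division cyclins, -1.10 to -0.86 for the sex body, 0.053 to 0.28 for germ granules, -0.094 to 0.21 for autosomal copies, 0.028 to 0.72 for spermatogonia, 1.19 to 1.60 for glycolysis, -0.020 to 0.15 for ribosomal proteins and -0.54 to -0.29 for the core spliceosome. Immediate early and heat shock genes ranged from 0.010 to 0.39. Division cyclins and the sex body were called without spermatocyte replicate 1 and without replicate 2. Where 1 spermatocyte sample is left, it is assumed to vary like the spermatids. Genes higher in spermatids numbered 10444 to 11532 and genes higher in spermatocytes 7821 to 11077. No paired analysis was possible because the labels give the groups no shared replicate numbers. The mitochondrial list gave no value under any alternative. Splits of 2 against 3 samples were not counted, since the spermatocytes have only 2 samples. In the simulation with 200 genes changed, 0 of 23 genes changed by 2-fold were called at means of 10 to 30, but depth was not varied and the share of genes changed also set the recovery.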

Other observations

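The symbol families, the weighing of 3 patterns and their tests below were chosen after the data were seen, except that the tests of short transcripts and of reads exchanged between libraries were written down before their results. Among 193 families of symbols with 10 or more tested members, 8 passed camera with the preset correlation, and none of the 193 passed with an estimated correlation (lowest adjusted p = 0.97). Olfactory receptor genes (Olfr), known from the nose, had 63 of 88 tested members higher in spermatids and 13 lower, with a median log2 fold change of 4.31 (camera adjusted p = 0.0013). Spermatogenesis-associated genes (Spata) had 21 of 25 higher and 2 lower, testis-expressed genes (Tex) 20 of 29 and 6, tubulin tyrosine ligase-like genes (Ttll) 11 of 13 and 2, and the clustered protocadherins Pcdhb 13 of 13 and 0. Collagen genes (Col) had 32 of 43 higher and 3 lower, with a median of 2.04. The myoid, endothelial, macrophage and blood markers, which include 3 of these collagen genes, moved the same way (19 of 28 higher, median 2.32), so the change in collagen genes cannot be told apart from a change in such cells. All 11 Srsf splicing factor genes were lower in spermatids (median -1.26, camera adjusted p = 0.0065), and of 28 RNA polymerase subunit genes (Polr) 16 were lower and 3 higher (camera adjusted p = 0.049). The Srsf genes also belong to the splicing regulator list, so their change is not separate from that list's result. The balance of calls in each of these 8 families kept its direction with equal library totals, TMM factors and quantile normalization.

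Rows without a symbol leaned the other way from named genes with the deposited scaling. Of 9740 such rows tested, 31.2% were higher in spermatids and 46.4% higher in spermatocytes, against 45.5% and 31.4% of 18630 rows with a symbol. The opposite lean was lost with equal totals, where 25.5% and 55.9% of rows without a symbol and 33.1% and 46.1% of rows with one were called, and after quantile normalization (27.7% and 52.0%, 35.7% and 44.2%), though rows without a symbol still leaned further toward spermatocytes. This difference between kinds of row was not tested.

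Transition protein and protamine transcripts were higher in spermatid replicate 1 than in replicates 2 and 3, with log2 ratios from 0.23 to 2.05 (median 1.34, SD 0.60 over 8 genes). Leydig markers (median log2 ratio -0.72) and myoid, endothelial, macrophage and blood markers (-0.53) were lower there. The median over all tested genes was 0.0076, but the size factors themselves bring this median near 0, so it cannot test for a scaling error. A wrong factor for that library would move all genes alike, so it would not set this list apart from the other genes. Enrichment of short transcripts was weighed with 10000 lists matched on transcript length in 4 bins. The list lay at their percentile 100 (95% of them from -0.04 to 0.54). The matched genes were longer (median 968 against 518 bases) and less abundant (median 12834 against 92935). Few genes are as short and as abundant as the protamines. The test therefore cannot decide whether transcripts as short as these were enriched, which stays open. A larger share of late spermatids in that fraction also stays open as a hypothesis. These genes exceeded acrosome genes, which start earlier, by 1.12 in median log2 ratio, but that restates the pattern on the genes that showed it and is no support.

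Of genes over 32-fold higher in spermatids and at 1000 or more there, 1251 in all, the spermatocyte level was a similar small part of the spermatid level, 1.41% at the median and 0.95% to 2.66% from the 5th to the 95th percentile, with 12 genes below 0.5%. The upper end is set by the choice of genes. Slx, with no read in either spermatocyte library, is among these 12 and departs from a common share, though its level is uncertain. Sirpb1c, with means of 3.16 in spermatocytes and 1011 in spermatids, also lies below 0.5%, and its level is uncertain too. Spermatid RNA carried into the spermatocyte fraction is a candidate explanation: the genes' median log2 ratio of spermatocyte replicate 1 to 2 was 0.44, outside the -0.05 to -0.0042 of 1000 lists matched on spermatocyte level, but its SD of 0.60 was above their 0.48, where a common admixture was predicted to give no larger spread. Reads exchanged between libraries during sequencing predict a like floor in spermatids, and the 10 lowest of 3678 abundant spermatocyte genes kept 1.23% of their level there, with 1 gene below the bound of 0.71%. Neither is decided by these values, and they cannot be told apart from each other or from low transcription in spermatocytes. The 8 transition protein and protamine genes, Spz1, Atp1a4 and Cstf2 are also among the 1251 genes. If RNA was carried over or reads were exchanged, the folds given for such genes are too small.

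Sertoli cell transcripts were higher in the spermatocyte samples. Leydig cell markers went the same way (median log2 fold change -3.52, 14 of 15 genes), but myoid, endothelial, macrophage and blood markers went toward spermatids (median 2.32, bootstrap SE 0.58). A lower share of germ cells in the spermatocyte fraction would raise the markers of every other cell type alike. The opposite directions argue against it as the whole cause only if these markers measure the content of such cells. Whether germ cells express the myoid, endothelial, macrophage and blood markers was not tested. Sertoli cells or their RNA in the spermatocyte fraction stay open as a hypothesis. That 96.2% of the list was higher there, including its 5 most abundant genes, led by Clu at 47612 and Ctsl at 11481, is the pattern itself and no support for a source. How far the sedimentation removed such cells was not measured here. Of the list 1 gene is also in another list, and expression of the others by germ cells was not tested. The Sertoli genes were higher in spermatocyte replicate 2 than 1 for 25 of 26 members (median log2 ratio 0.41).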
